A study of Mus musculus with 6 samples.

How the data were processed

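Leukocytes of normal and AML-infiltrated mouse lungs were profiled, 3 libraries per group, with the 10x Genomics single-cell 3' kit v3.1 after enrichment of CD45-positive cells on magnetic beads, per the labels' protocols. The deposited matrices hold whole-number UMI counts per gene and barcode, not normalized, for 32285 features, made with Cell Ranger 7.0.0 on the mm10 build, per the submitters' processing notes. The filter that made the deposited barcode lists is not given in the sources used here. The groups and the replicate numbers come from the labels. No pair of libraries of one group agreed within sampling noise, since the chi-square per degree of freedom lay between 46.2 and 178, so each was counted as its own sample.

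Cells with at least 200 genes, at least 500 UMIs and under 10% of UMIs from mitochondrially encoded genes were kept, 71634 of 73095 barcodes. Doublets were called per library with Scrublet in scanpy 1.11.5. Scrublet's own threshold marked 0% of the cells of normal lung replicate 3 and AML lung replicate 3, so the median threshold of the other libraries, 0.209, was used there, a choice made after seeing those calls. It marked 3.15% and 1.53% of them, against 1.76% to 5.87% elsewhere. All 71634 kept cells, predicted doublets included, were scaled to 10000 counts, log-transformed and reduced to 30 principal components of 2000 variable genes. Leiden clustering (leidenalg 0.10.2) used 15 neighbours at resolution 1, without integration of libraries. The clusters and their names thus include predicted doublets. The 2035 doublets were left out of the comparisons afterwards, which left 69599 cells. Sex-linked, mitochondrial, ribosomal, haemoglobin and antigen receptor genes were kept out of the variable genes.

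Of 33 clusters 28 were named "X-like" from marker lists of 23 cell types fixed before the data were examined. A cluster needed at least 3 markers raised, and stayed unnamed if a second type scored at least 0.6 of the best, a ratio set after seeing the clusters, or if cycling genes, predicted doublets or markers of another type led it. Unnamed clusters held 4.09% ± 0.850 of cells in AML lung and 5.43% ± 0.332 in normal lung (SD, n = 3). The ratio kept out cluster 28, which has B cell and neutrophil markers and held 0.550% of cells in AML lung and 0.0524% in normal lung. Cell types were rebuilt here, and other names are possible.

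Counts were summed per library and class, or over every barcode for whole libraries, and tested with edgeR 4.0.16 in R 4.3.3, using TMM normalization, filterByExpr and the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. A library with fewer than 20 cells of a class was left out. CPM values of tested genes are scaled to these sums with TMM-scaled library sizes. Those of the Y-linked, Xist, HOX and haemoglobin genes, of the genes in the closing observations on whole libraries of S100a8 and Cd300e in the smaller classes and of the free RNA and caught cell tests use the plain sums. The standard error of a log2 change was derived as its size over the square root of F. Shares per library were compared with the exact two-sided permutation test over 20 arrangements, whose smallest p is 0.1, so no share can reach 0.05. In total 27 gene lists, fixed before the data were examined, were tested with camera (limma 3.58.1, preset correlation 0.01, at least 5 measured members), with an estimated correlation and with fry. Of the 87 calls, none held with the estimated correlation and 5 held with fry, which called 6 lists in all. DESeq2 1.42.0, RLE size factors, no low count filter, the replicate number as a block, leaving out each library, stricter cell filters, doublets kept, resolution 2, naming each cell by its marker score and equal numbers of cells per library were alternatives. Positions come from the GENCODE annotation of GRCm38, the assembly also called mm10.

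Genes named in the text are the 6 largest increases and the 6 largest decreases of each main class among genes past the threshold with an average log2 CPM of at least 5 and no overlap between groups, and up to 15 members of the fixed lists by p. Unnamed gene models, ribosomal, mitochondrial and antigen receptor genes were left out. Nonclassical monocytes were planned as a secondary class and were given the full treatment after their calls were seen. Unnamed clusters were searched for cells more frequent in every AML library than in every normal one. After the outcome was seen, this search was limited to clusters with most of their cells outside the named classes, which set aside a cluster at resolution 2 led by Spic and Il10, since genes that lead it differ between the groups and its size is then not a separate result. Intervals cover counting error only, at 95%.

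Tested on simulated counts drawn from the real means with known changes, edgeR recovered 64.3% of genes changed 2-fold and 96.9% of those changed 4-fold in nonclassical monocyte-like cells, and 63.3% and 90.9% in classical monocyte-like cells. Recovery at these sizes was 32.3% and 76.3% in alveolar macrophages, 3.16% and 62.2% in neutrophils, 6.32% and 61.9% in T cells, 12.8% and 78.4% in NK cells, 9.09% and 68.0% in B cells, 4.40% and 55.6% in interstitial macrophages and 40.4% and 79.4% in whole libraries. Of the simulated calls in alveolar macrophages 13.2% were false, the highest of these comparisons, and 3.80% in classical monocytes, the lowest. Each gene was drawn independently, without shifts that many genes of a library share, so recovery in the real data may differ. Free RNA, which droplets take up from broken cells, was estimated per class and library from marker genes of other types, as their level relative to the whole library. It was estimated for the main classes except interstitial macrophages.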

Results

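Single-cell RNA libraries were made from CD45-positive cells, the leukocyte fraction, of perfused and enzyme-digested mouse lungs. Libraries from 3 normal lungs and from 3 lungs infiltrated by acute myeloid leukaemia (AML), a cancer of myeloid precursors, were compared, and the series asks how the immune microenvironment of a tissue differs when leukaemia is present. The labels name neither the leukaemia model nor which cells are leukaemic. The 6 libraries held 73095 barcodes, and the total count per library ranged from 43913245 to 66513826 UMIs. Depth per cell was uneven. The median was 9354, 6102 and 2740 UMIs per barcode in normal lung replicates 1, 2 and 3, and 9381, 3979.5 and 1067 in AML lung replicates 1, 2 and 3, so the 35391 barcodes of AML lung replicate 3 were the shallowest. After filtering, 69599 cells were used. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. The level of Xist, scaled to the library total (CPM), lay between 710 and 955 in the 6 libraries, and Ddx3y, Eif2s3y, Kdm5d and Uty were each at 0.121 CPM or lower.

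Nonclassical monocyte-like cells, the patrolling monocytes named here from Ace, Treml4, Cd300e and related markers, made up 35.4% ± 18.8 (SD, n = 3) of cells in AML lung and 9.93% ± 1.17 (SD, n = 3) in normal lung. Interstitial macrophage-like cells held 1.08%, 1.14% and 1.45% of cells in the AML libraries and 0.399% ± 0.148 in normal lung. Late neutrophil precursor-like cells, which carry the secondary granule genes Ngp, Camp and Ltf, held 1.19% ± 0.335 in AML lung and 0.0168% ± 0.0158 in normal lung, where 0, 1 and 3 such cells were found. With 0 of the 3442 cells of normal lung replicate 1, a share of up to 0.0872% remains possible there. B cell-like cells were fewer, at 9.40% ± 2.93 in AML lung and 18.0% ± 2.85 in normal lung. In each of these 4 classes the 3 AML libraries lay on one side of the 3 normal libraries. The exact two-sided permutation test gave p = 0.1 for each, the smallest p that 3 against 3 libraries allow, and 0.375 after adjustment over 15 classes.

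**Figure D1:**
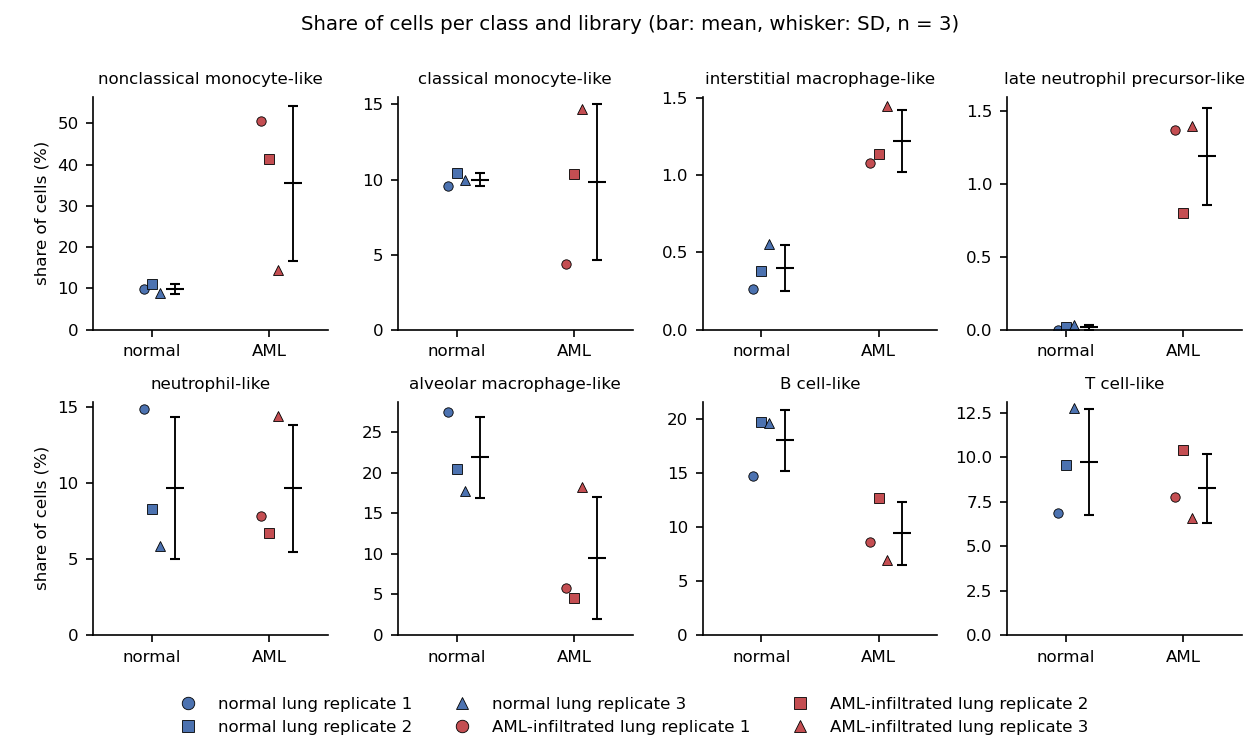
Share of cells (%, vertical axis) of 8 classes in normal and AML-infiltrated lung, 1 point per library, with the mean and SD of 3 libraries beside the points. Nonclassical monocyte-like cells took 14.4% to 50.5% of cells in the AML libraries and 8.81% to 11.1% in the normal ones, and the neutrophil-like shares of the groups overlap.

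Alveolar macrophage-like cells, the resident phagocytes of the airspace, held 5.74%, 4.56% and 18.2% of cells in the AML libraries and 21.9% ± 5.03 in normal lung (exact permutation p = 0.2), with AML lung replicate 3 inside the range of the normal libraries. Neutrophil-like cells held 9.65% ± 4.18 in AML lung and 9.64% ± 4.67 in normal lung (exact permutation p = 1). Classical monocyte-like cells held 9.83% ± 5.18 and 9.99% ± 0.426 (exact permutation p = 0.9), T cell-like cells 8.26% ± 1.94 and 9.74% ± 2.98 (p = 0.6), and NK cell-like cells 5.60% ± 1.45 in AML lung and 5.61%, 5.27% and 8.01% in the normal libraries (p = 0.6). The T cell share leaves out unnamed cluster 23, which scored best as T cells and was led by Il23r, Icos and Ctla4. It held 1.40% of cells in AML lung, 0.358% in AML lung replicate 3, and 2.54% in normal lung. Cluster 9, led by Ikzf2 and Ctla4, was counted as T cells. It held 2947 cells, 1983 of them from AML lung replicate 3, doublets included. Which T cells enter the class may thus differ between libraries. Shares depend on the CD45 enrichment and sum to a whole, so a class that takes more of the cells lowers the others. Without nonclassical monocytes in the total, an alternative chosen after seeing the data, the B cell-like difference was -4.32 percentage points in place of -8.62, and the groups overlapped, with 17.3%, 21.6% and 8.14% in AML lung replicates 1, 2 and 3 and 16.3%, 22.1% and 21.6% in the normal libraries.

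Nonclassical monocyte-like cells showed the most changed genes of the classes tested. Il10, which encodes an anti-inflammatory cytokine, stood at 98.0 ± 69.1 CPM in AML lung and 0.703 ± 0.430 CPM in normal lung (SD, n = 3), a log2 change of 7.16 (SE 0.73, edgeR adjusted p = 0.00230). The normal libraries held only 8 Il10 UMIs in these cells against 6461 in the AML libraries, and the ratio of pooled CPM was 160 with a 95% counting interval of 81.0 to 370. Mmp14, a membrane-bound matrix metalloproteinase, rose from 2.27 ± 0.489 to 62.5 ± 29.0 CPM (log2 change 4.78, SE 0.45, adjusted p = 0.00212). Ikbke, a kinase of the innate interferon response, rose by 3.99 on the log2 scale (SE 0.30), Hpgds, a prostaglandin D synthase, by 3.90 (SE 0.45), Siglece, an inhibitory sialic acid receptor of myeloid cells, by 3.12 (SE 0.39), and Tnip3, which is also in the fixed marker list of cDC2, by 2.85 (SE 0.36).

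Among the genes that fell in nonclassical monocyte-like cells, Apoe, a lipid carrier and a marker fixed for interstitial macrophages, went from 1764 ± 464 to 412 ± 230 CPM (SD, n = 3, log2 change -2.10, SE 0.36, edgeR adjusted p = 0.0137). Flt1, a VEGF receptor, had a log2 change of -2.67 (SE 0.64), Abca9, a lipid transporter of the ABC family, of -2.64 (SE 0.57), and the adhesion receptor gene Adgrl3 of -2.58 (SE 0.62). Hpgd, which inactivates prostaglandins, changed by -2.22 (SE 0.51) and Serpinb2, a plasminogen activator inhibitor, by -2.06 (SE 0.42). In all, 481 genes were higher and 312 lower in AML lung among 10438 tested. That count of 793 became 110, 197 and 178 without normal lung replicates 1, 2 and 3, 247 without AML lung replicate 1 and 1933 without AML lung replicate 3. Different clusters held most of this class in the groups, with clusters 0 and 1 in AML lung and cluster 17 in normal lung, and Il10 was among the genes leading cluster 0. At resolution 2, 1285 cells of this class lay in a cluster that took no name, led by Spic, Il10, Hmox1 and Tnip3, with Hpgds and Mmp14 among its leading genes. It held 14.6%, 4.57% and 0.190% of cells in AML lung replicates 1, 2 and 3 and 0.0380% to 0.116% in the normal libraries. With it outside the class the log2 change of Il10 was 7.26, of Mmp14 4.61, of Hpgds 3.59 and of Tnip3 2.63, all still past the threshold.

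Gene lists fixed beforehand placed these changes in groups. Of 7 measured genes of alternative activation and immunosuppression, 5 were higher and 1 lower in nonclassical monocyte-like cells, and 5 and 1 adjusted over the list alone. They include Cd274, the gene of the checkpoint ligand PD-L1, at 400 ± 112 against 139 ± 43.6 CPM (log2 change 1.52, SE 0.26, edgeR adjusted p = 0.0128), Il1rn, the interleukin 1 receptor antagonist (2.34, SE 0.33), and Socs3, a cytokine signalling suppressor (1.18, SE 0.21). The list was called by camera (adjusted p = 8.21e-06), with adjusted p = 0.363 with an estimated correlation. Of 14 inflammatory cytokine and NF-kB target genes, 4 were higher, and 7 higher and 1 lower adjusted over the list alone. Il1b, a pyrogenic cytokine, changed by 1.42 (SE 0.20) and Sod2, the mitochondrial superoxide dismutase, by 1.71 (SE 0.20), and camera gave adjusted p = 0.000227, or adjusted p = 0.484 with an estimated correlation.

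Oxidative phosphorylation genes had a median log2 change of 0.41 in nonclassical monocyte-like cells, with 6 of 30 higher and 10 higher adjusted over the list alone (camera adjusted p = 3.13e-06, and adjusted p = 0.484 with an estimated correlation). Unfolded protein response genes had a median of -0.63, with 1 of 12 lower and 8 lower adjusted over the list alone (camera adjusted p = 4.83e-05, and adjusted p = 0.484 with an estimated correlation). The scavenger receptor genes Msr1 (log2 change -1.81, SE 0.15) and Cd36 (-0.98, SE 0.18) and the transcription factor gene Mef2c (-1.40, SE 0.17) were lower, while Fcgr4, the gene of an activating Fc receptor, was higher (1.43, SE 0.19). Ldha, which makes lactate, Ctsd, a lysosomal protease, and the interferon-induced gene Ifit3 were higher by 0.85, 1.09 and 2.71 on the log2 scale. Of the 8 nonclassical monocyte markers themselves none passed edgeR's adjusted threshold, and their median log2 change was 0.15. Of the 5 measured interstitial macrophage markers 2 were higher and 2 lower, and of the 4 alveolar macrophage markers 2 were higher. Of the 6 classical monocyte markers 1 was higher and 1 lower, and of the 7 neutrophil markers 1 was lower. The 4 erythroid markers had a median log2 change of 3.31, with none past the threshold.

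In classical monocyte-like cells, the Ly6c2- and Ccr2-expressing monocytes, Lcn2, an iron-sequestering granule protein, stood at 87.7 ± 25.9 CPM in AML lung (SD, n = 3) and at 3.47, 4.10 and 1.42 CPM in the normal libraries (log2 change 4.86, SE 0.34, edgeR adjusted p = 0.000620). S100a8 and S100a9, which encode the calprotectin subunits, stood at 414 ± 209 against 16.9 ± 4.51 CPM (4.61, SE 0.38) and 215 ± 56.1 against 21.6 ± 6.11 CPM (3.31, SE 0.24). Prtn3, a primary granule protease of myeloid precursors, rose from 10.9 ± 2.22 to 120 ± 47.7 CPM (3.45, SE 0.33), Saa3, a serum amyloid, by 4.75 on the log2 scale (SE 0.51), and the adhesion molecule gene Pecam1 by 2.84 (SE 0.37). By the fixed marker lists, S100a8 and S100a9 are also markers of neutrophils, Lcn2 of late neutrophil precursors, Prtn3 of immature myeloid cells and Pecam1 of endothelium.

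The genes with the largest decreases in classical monocyte-like cells were Lpl, the lipoprotein lipase, at 13.8 ± 4.10 against 88.9 ± 59.2 CPM (log2 change -2.74, SE 0.43, edgeR adjusted p = 0.0210), Adgrl3 (-1.49, SE 0.27), Chn2 (-1.37, SE 0.16), Rnf150 (-1.34, SE 0.21), the phosphoinositide phosphatase gene Inpp4b (-1.34, SE 0.25) and Sulf2, which edits heparan sulfate (-1.27, SE 0.16). Of 10774 genes tested, 123 were higher and 75 lower. The count of 198 became 19, 18 and 29 without normal lung replicates 1, 2 and 3, 101 without AML lung replicate 1 and 1048 without AML lung replicate 3. Cluster 10 held most of this class in the other libraries and cluster 2 most of it in AML lung replicate 3. Of the markers of other types measured in this class, 3 of 7 neutrophil genes, 3 of 4 late neutrophil precursor genes and 2 of 4 immature myeloid genes were higher. Of the 8 nonclassical monocyte markers 1 was higher, with a median log2 change of 0.43, and of the 3 cDC2 markers 1 was higher and 1 lower.

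**Figure D2:**
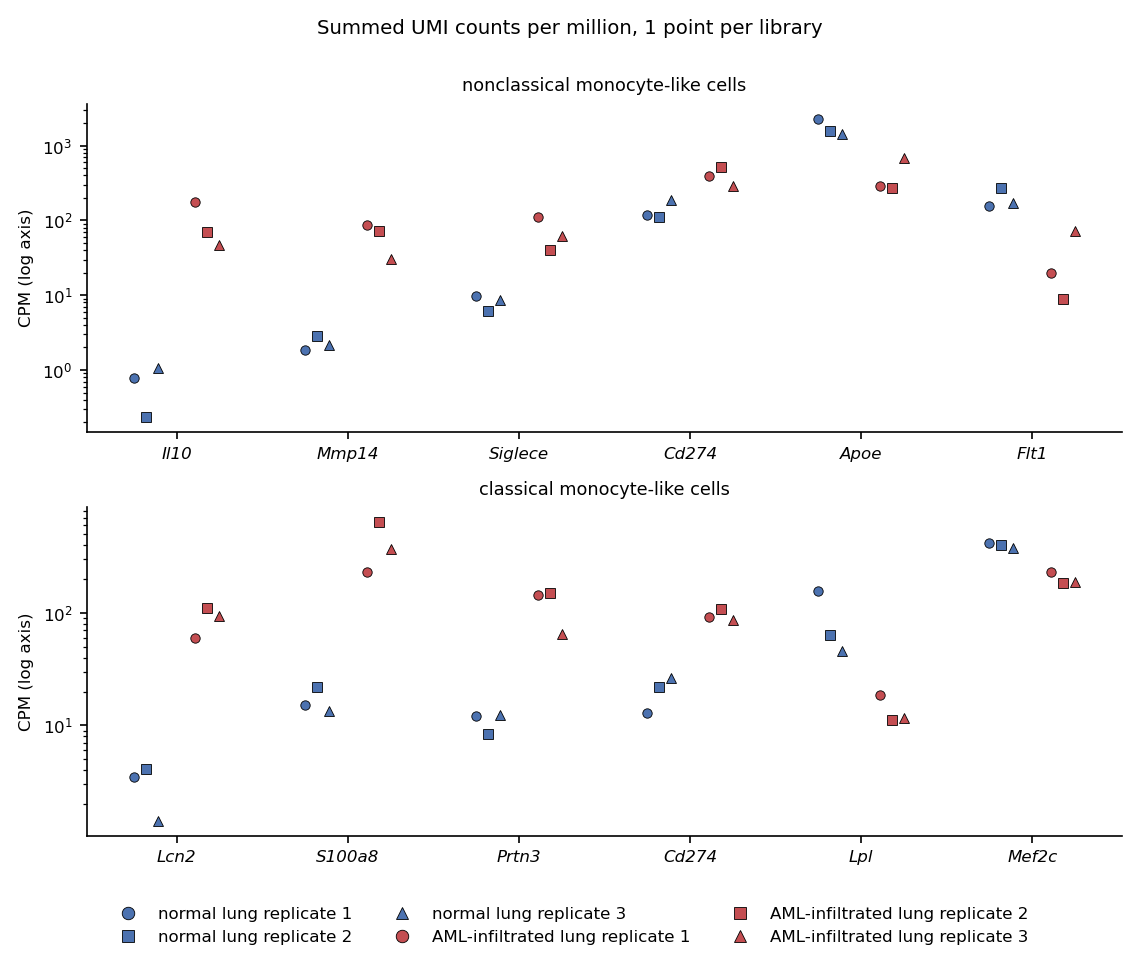
CPM (vertical axis, log scale) of named genes in nonclassical and classical monocyte-like cells, 1 point per library, with normal lung at the left of each gene and AML lung at the right. Il10 lies between 47.5 and 177 CPM in the AML libraries and at 1.08 CPM or lower in the normal ones.

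In classical monocyte-like cells 5 of 12 measured genes of alternative activation and immunosuppression were higher, and 6 adjusted over the list alone. Cd274 stood at 95.6 ± 12.2 against 20.3 ± 6.80 CPM (SD, n = 3, log2 change 2.23, SE 0.23, edgeR adjusted p = 0.00384), and Pdcd1lg2, the gene of the related ligand PD-L2, at 5.47 ± 0.836 against 1.19 ± 0.743 CPM. Il10 was at 10.9 ± 7.28 CPM against 0.464 ± 0.130, from 183 and 7 UMIs, with a ratio of pooled CPM of 21.0 and a 95% counting interval of 10.0 to 53.1. Camera called this list (adjusted p = 8.21e-06), with adjusted p = 0.150 with an estimated correlation. Of 15 proliferation genes 3 were higher, Stmn1 by 2.64 on the log2 scale (SE 0.50), and 6 adjusted over the list alone (camera adjusted p = 0.000182, and adjusted p = 0.583 with an estimated correlation). Gapdh and Ldha, which act in glycolysis, were higher by 0.94 and 0.83, while the hexokinase gene Hk2 and the matrix protein gene Thbs1 were lower, at -1.22 and -1.06.

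A list of HOX and MEIS genes that mark many leukaemias was not higher, over its measured genes, in classical monocyte-like cells. Its median log2 change was -0.20 over 6 measured genes, with 1 lower, Mef2c (log2 change -0.99, SE 0.13, edgeR adjusted p = 0.0119), and 2 lower adjusted over the list alone. Camera gave adjusted p = 0.0182 for a decrease, with adjusted p = 0.583 with an estimated correlation and adjusted p = 0.0879 without AML lung replicate 2. In whole libraries Hoxa9 reached at most 0.511 CPM and Hoxa10 at most 0.0403 CPM, and no cluster took the name of immature myeloid cells. Hoxa10, with at most 2 UMIs in a library, cannot pass the low count filter in this class. Hoxa9 had at most 34 UMIs in a whole library, and its level within this class is not given here. The list thus rests mainly on its other genes and cannot tell whether leukaemic cells were present. Hoxa9 and Hoxa10 are also in the marker list of immature myeloid cells, which makes that name harder to reach.

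Interstitial macrophage-like cells, the macrophages of the lung connective tissue, could be tested with 3 AML and 2 normal libraries, since normal lung replicate 1 held fewer than 20 of them. Ccl5, a chemokine for T cells and monocytes, stood at 463 ± 119 CPM (SD, n = 3) in AML lung and 26.9 ± 15.2 CPM (SD, n = 2) in normal lung (log2 change 4.10, SE 0.45, edgeR adjusted p = 0.0376), and Dusp5, a nuclear ERK phosphatase, rose by 2.47 (SE 0.34). The normal level of Ccl5 rests on 7 and 3 UMIs in normal lung replicates 2 and 3, against 293, 334 and 484 in AML lung replicates 1, 2 and 3. Ccl5 was also among the genes leading the NK cell clusters, and free RNA was not estimated for the interstitial macrophage class. The cytokine gene Il6 went from 115 ± 49.5 to 11.8 ± 5.16 CPM (-3.22, SE 0.46) and Vegfa, the endothelial growth factor, from 96.6 ± 30.2 to 12.4 ± 4.30 CPM (-2.97, SE 0.43). Prkg1 (-5.25, SE 0.82), Apbb2 (-3.24), the oxysterol receptor gene Gpr183 (-2.90), Mir99ahg (-2.84) and the complement receptor gene C3ar1 (-2.12) were lower too. Of 7760 genes tested 2 were higher and 22 lower. That count of 24 became 43 without normal lung replicate 2 and 2 without normal lung replicate 3, fits with 1 normal library in which the AML libraries alone give the spread, and 2, 0 and 89 without AML lung replicates 1, 2 and 3 (at 0 by edgeR, 775 had an unadjusted p under 0.05, and DESeq2 called 161 over all libraries), and 0 when cells were named by their own marker scores, where 758 had an unadjusted p under 0.05.

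MHC class II genes, which present antigen to helper T cells, had a median log2 change of -1.41 in interstitial macrophage-like cells. None of the 8 measured passed the threshold over all genes by edgeR, and 7 were lower adjusted over the list alone, H2-Eb1 at 1394 ± 561 against 3808 ± 971 CPM and Cd74 at 4785 ± 1927 against 12620 ± 2459 CPM (SD, n = 3 and 2). Camera gave adjusted p = 5.39e-08, with adjusted p = 0.376 with an estimated correlation. The markers of cDC2, a dendritic cell with abundant MHC class II, had a median log2 change of -1.80 in this class, those of B cells, which also present antigen, -1.42, and those of neutrophils 3.07, with none of the 5, 5 and 4 past the threshold. The class's own 10 markers had a median of -1.02 and the 8 of nonclassical monocytes 0.90, between 0.25 and 2.09, again with none past the threshold by edgeR.

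Alveolar macrophage-like cells had 0 of 12100 genes past the threshold by edgeR, with 1274 at an unadjusted p under 0.05 and 130 by DESeq2, and 1 without AML lung replicate 3. With the replicate number as a block edgeR called 34. Lipid-associated macrophage genes were lower as a list, with a median log2 change of -0.24 and, adjusted over the list alone, 4 of 16 lower and 1 higher. They include Gpnmb, a lysosomal glycoprotein, at 101 ± 26.0 against 212 ± 24.1 CPM, and the fatty acid binding protein gene Fabp5 at 323 ± 39.6 against 503 ± 39.8 CPM (SD, n = 3). Camera gave adjusted p = 1.07e-05, with adjusted p = 0.448 with an estimated correlation. Markers of neutrophils had a median log2 change of 3.50 in these cells, those of classical monocytes 2.92 and the class's own 11 markers -0.41. By the highest of the marker lists, other cells' RNA reached 0.881%, 21.6% and 51.1% of the whole library level in AML lung replicates 1, 2 and 3. In normal lung replicates 1, 2 and 3 it reached 1.12%, 1.61% and 14.0%.

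Neutrophil-like cells had 0 of 7836 genes past the threshold by edgeR, with 862 at an unadjusted p under 0.05 and 85 by DESeq2. Type I interferon response genes had a median log2 change of 0.67 there, and 7 of 25 were higher adjusted over the list alone. Zbp1, a nucleic acid sensor, stood at 114 ± 26.4 against 27.3 ± 2.07 CPM and Irf7, a transcription factor of the interferon response, at 93.4 ± 17.9 against 44.6 ± 4.40 CPM (SD, n = 3). Camera gave adjusted p = 3.62e-07 for the list, with adjusted p = 0.595 with an estimated correlation and adjusted p = 0.0917 without AML lung replicate 1. Without AML lung replicate 1 there were 125 changed genes and without AML lung replicate 3 there were 90. Late neutrophil precursor markers had a median log2 change of 3.11 in this class, those of classical monocytes 1.06, those of nonclassical monocytes 0.93 and those of erythroid cells -3.88, with none past the threshold. The haemoglobin gene Hbb-bs stood at 0.330, 11050 and 6299 CPM in normal lung replicates 1, 2 and 3 and at 0, 0 and 1588 CPM in AML lung replicates 1, 2 and 3. At resolution 2, 1199 of the 5004 cells of this class in AML lung replicate 3 lay in an unnamed cluster with markers of classical monocytes and neutrophils, led by Saa3 and Vcan, against 0 to 27 cells in the other libraries. With that cluster outside the class edgeR again called 0 genes, with 790 at an unadjusted p under 0.05.

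T, NK and B cell-like cells held type I interferon response genes at higher levels in AML lung, as lists. In T cell-like cells the median log2 change was 1.12, and 13 of 25 genes were higher adjusted over the list alone. In NK cell-like cells it was 1.17, with 11 of 18, and in B cell-like cells 1.31, with 12 of 24. Irf7 stood at 38.2 ± 9.25 against 17.5 ± 0.858 CPM in T cells, 33.7 ± 9.91 against 13.5 ± 2.66 in NK cells and 31.7 ± 15.5 against 7.21 ± 2.77 in B cells (SD, n = 3), and Ifit3, an antiviral effector, at 15.7 ± 2.76 against 4.44 ± 1.08 CPM in B cells. Camera gave adjusted p = 1.21e-17, 3.39e-11 and 2.37e-17 in T, NK and B cells, with adjusted p = 0.203, 0.446 and 0.403 with an estimated correlation.

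Over all genes 0 were past the threshold in T, NK and B cell-like cells by edgeR. At an unadjusted p under 0.05 there were 883, 1202 and 1146, DESeq2 called 10, 64 and 15, and edgeR without AML lung replicate 3 called 45 in NK cells. With the replicate number as a block, which was not taken to pair the samples, edgeR called 269, 55 and 71. NK receptor and maturation genes had a median log2 change of -0.28 in NK cell-like cells, with 0 of 19 lower over all genes by edgeR and 2 adjusted over the list alone. They include Prdm1, a regulator of effector differentiation, at 67.0 ± 20.2 against 147 ± 8.54 CPM, and the activating receptor gene Cd226 at 67.3 ± 17.9 against 136 ± 23.5 CPM (SD, n = 3, camera adjusted p = 4.53e-05, adjusted p = 0.558 with an estimated correlation and adjusted p = 0.0575 without AML lung replicate 3). The 8 markers by which NK cells were named had a median of -0.42, with none past the threshold. Markers of nonclassical monocytes had median log2 changes of 2.52, 3.08 and 3.79 in the T, NK and B cell classes, and those of neutrophils 2.44, 3.41 and 2.71, while those of erythroid cells had -3.23 in the B cell class, with none past the threshold. By the highest of the marker lists, the level of other cells' RNA in the T cell class reached 88.4% of the whole library level in AML lung replicate 3, 18.7% and 16.3% in AML lung replicates 1 and 2, and 8.11%, 5.12% and 38.2% in normal lung replicates 1, 2 and 3. In AML lung replicate 3 it reached 78.7% in the NK and 90.1% in the B cell class, and in normal lung replicate 3 19.1% and 18.3%.

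Among the remaining classes cDC2-like cells, dendritic cells that prime helper T cells, had 2 changed genes, both higher. They were Ly6a and Isg15, named here after their values were seen. That count became 9 without AML lung replicate 1, 3 without AML lung replicate 3 and 0 by edgeR without AML lung replicate 2 or any 1 of the normal libraries, where 502, 692, 591 and 767 had an unadjusted p under 0.05. DESeq2 called 47 over all libraries. By edgeR 0 genes changed in cDC1-, pDC-, ILC2-, mature DC- and endothelial-like cells, where 759, 686, 252, 228 and 1686 had an unadjusted p under 0.05 and DESeq2 called 55, 14, 4, 5 and 350. With the replicate number as a block cDC1 had 4 and pDC 232. With single libraries left out, cDC1 reached 3 without normal lung replicate 3 or AML lung replicate 1, pDC 2 without AML lung replicate 3, ILC2 26, 42, 286 and 155 without normal lung replicates 2 and 3 and AML lung replicates 2 and 3, and mature DC 25 and 117 without AML lung replicates 2 and 3. ILC2 and mature DC had 2 libraries per group, so these fits leave 1 library in a group and the other group alone gives the spread. Type I interferon genes had median log2 changes of 0.77, 0.72, 0.75 and 0.71 in cDC1-, cDC2-, pDC- and endothelial-like cells (camera adjusted p = 2.24e-09, 3.50e-11, 1.25e-05 and 1.45e-05), with adjusted p = 0.272, 0.253, 0.355 and 0.262 with an estimated correlation. Adjusted over the list alone, 5 of 13, 6 of 21, 4 of 18 and 4 of 25 were higher. Genes of other cells differed in these classes too. The neutrophil gene S100a8 had means of 322, 528, 773 and 598 CPM in AML lung and 79.4, 8.99, 12.7 and 78.8 CPM in normal lung, and the nonclassical monocyte gene Cd300e 35.3, 23.3, 31.4 and 85.5 CPM against 7.40, 3.68, 0 and 5.90 CPM. For S100a8, AML lung replicate 3 made up most of the mean in cDC1-, cDC2- and endothelial-like cells, at 888, 1370 and 1730 CPM. AML lung replicate 1 stood there at 6.45, 9.85 and 46.3 CPM and replicate 2 at 71.0, 203 and 19.0 CPM. Normal lung replicate 1 reached 225 CPM in cDC1 and normal lung replicate 3 220 CPM in endothelial-like cells.

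**Figure D3:**
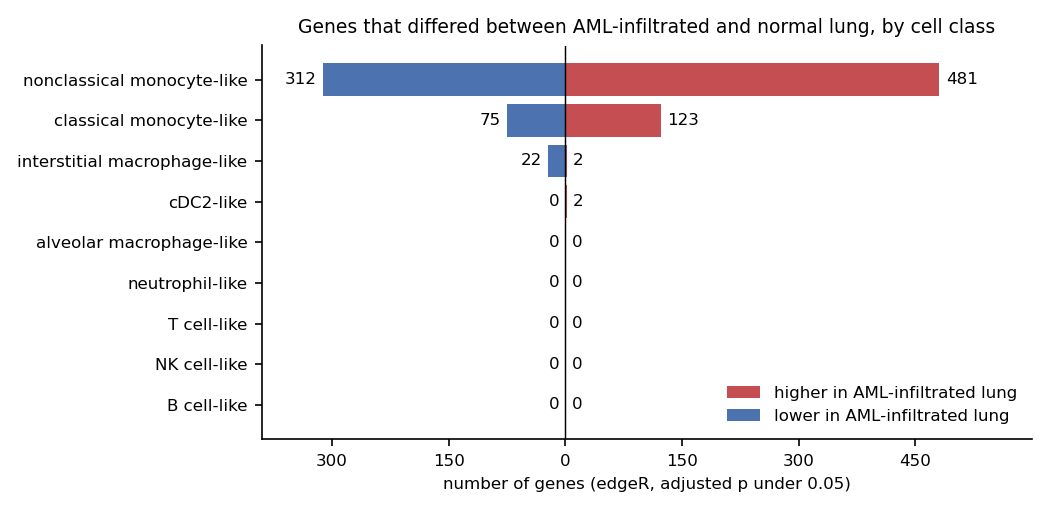
Number of genes (horizontal axis) higher or lower in AML-infiltrated than in normal lung at an adjusted p under 0.05 by edgeR, for 9 cell classes. Nonclassical monocyte-like cells have 481 higher and 312 lower genes, and 5 of the classes have 0.

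In whole libraries, summed over all barcodes without clusters or cell names, all 8 nonclassical monocyte markers were higher, Cd300e at 184 ± 73.1 against 26.1 ± 1.19 CPM (SD, n = 3, log2 change 2.81, SE 0.27, edgeR adjusted p = 0.00825) and Eno3, the muscle-type enolase, by 2.63 (SE 0.36). Fcgr4 (2.71, SE 0.18), Ms4a4a (2.56, SE 0.31), Smpdl3b (2.34, SE 0.25) and Lcn2 (2.80, SE 0.43) were higher too. Spp1, which encodes osteopontin, Lpl, Egfem1, Dnah11 and Clmn were lower, with log2 changes of -2.35, -2.25, -2.23, -2.22 and -1.94, and Nol4l stood at 39.8 ± 8.54 against 159 ± 77.8 CPM. Il10 stood at 50.3 ± 41.1 against 0.771 ± 0.311 CPM (log2 change 6.03, SE 0.72). Alveolar macrophage markers had a median log2 change of -1.70, with 3 of 11 lower.

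Type I interferon response genes were higher in whole libraries as well, with 16 of 26 past edgeR's threshold, 20 adjusted over the list alone and a median log2 change of 0.89 (camera adjusted p = 2.81e-17, and adjusted p = 0.324 with an estimated correlation). Irf7 rose by 1.38 on the log2 scale (SE 0.14) and Socs3 by 1.62 (SE 0.10). Of 15 glycolysis genes 9 were higher, and 10 adjusted over the list alone, Pgk1 by 0.77 (SE 0.10, camera adjusted p = 0.000268, and adjusted p = 0.324 with an estimated correlation). These sums do not separate the shares of cell types from the levels within them. Of 16856 genes tested 1042 were higher and 627 lower, and the count of 1669 became 118, 0 and 718 without normal lung replicates 1, 2 and 3 and 216, 430 and 3122 without AML lung replicates 1, 2 and 3. The balance of directions moved too. With the replicate number as a block 91 were higher and 3 lower, and without AML lung replicate 3 1449 were higher and 1673 lower. Where edgeR called 0, without normal lung replicate 2, 3610 genes had an unadjusted p under 0.05, and DESeq2 called 3493 over all 6 libraries. In coordinates of GRCm38, Il10 lies on chromosome 1 from 131019845 to 131024974, Cd274 on chromosome 19 from 29367455 to 29388095, Mmp14 on chromosome 14 from 54431612 to 54445364, Lcn2 on chromosome 2 from 32384633 to 32388252 and S100a8 on chromosome 3 from 90668978 to 90670035, each annotated as protein coding.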

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

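The tests without AML lung replicate 3, those on the most abundant markers and on the immature myeloid markers, the count without 1 AML library, the levels without a cycling cluster, and the splits of the libraries for counts of genes were chosen only after the results were seen, and the search of unnamed clusters was narrowed then. The remaining tests of free RNA, of caught cells and of splits for the interferon lists were set before their results were seen.

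Cells mostly outside the compared classes were more frequent in every AML library than in every normal one in 2 clusters at resolution 2. A cluster led by cycling genes and Gzma, a granzyme of cytotoxic lymphocytes, held a mean of 0.314% of cells in AML lung and 0.120% in normal lung. The groups lay close, with 0.202% in AML lung replicate 1, from 9 cells, and 0.189% in normal lung replicate 3, from 18 cells. A cluster led by cycling genes with Prtn3 and Elane, proteases of immature granulocytes, held a mean of 0.223% of cells in AML lung, from 5, 43 and 71 cells, and 0.00349% in normal lung, from 0, 0 and 1 cells. Of its 120 cells 18 lie in the classical monocyte class, where Prtn3 and Elane were also higher. Without them the mean level in that class was 9.39 CPM for Elane and 120 CPM for Prtn3 in AML lung, against 9.54 and 120 CPM with them. Neither difference in the size of a cluster was tested. The search ran over all unnamed clusters of both resolutions, so a separation of the groups can also arise by chance.

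The 793 changed genes of nonclassical monocyte-like cells were first set against free RNA. For the 481 higher genes free RNA could bring a median of 8.19% of the increase (quartiles 5.59% and 10.9%), which argues against it as the source. Dependence on a single AML library is argued against by the 247 genes still called without AML lung replicate 1, the fewest of these 3 fits. Without AML lung replicate 3 the count rose to 1933. Leaving out a normal library lowered it more, with 110 without normal lung replicate 1. Whether chance assignment of libraries could be the source stays open, because 3 against 3 libraries make 10 splits, too few for a share under 0.05, with 793 genes in the real split and 0 in the highest of the others. A difference tied to the leukaemia remains a hypothesis, and a difference between mice or runs was not tested.

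Type I interferon genes were higher as a list in T, NK and B cell-like cells, and RNA from other cells, at its highest estimate, may account for it over all libraries. By the highest of the marker lists free RNA could bring a median of 101.5%, 107.7% and 110.8% of the increase. The marker lists differed widely. In AML lung replicate 3 the lowest gave 6.16%, 3.3% and 4.33% of the whole library level in the T, NK and B cell classes. The highest gave 88.4%, 78.7% and 90.1% there, so whether free RNA is the source is not settled. Without AML lung replicate 3 the medians were 25.1%, 14.5% and -0.386%, with upper quartiles of 46.7%, 28.2% and 5.91%. These values cannot decide, since the free RNA of the normal libraries is subtracted and was also taken by the highest list. In normal lung replicate 3 that list gave 38.2%, 19.1% and 18.3%, which lowers the medians. Free RNA as the source stays open for every AML library. The splits cannot give a share under 0.05, with the real median difference at 0.88, 0.94 and 0.90 on the log2 scale and the highest other at 0.48, 0.47 and 0.60. These are differences of mean log2 CPM from plain sums with a constant added. They are therefore not the edgeR changes given in the Results.

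Neutrophil and precursor markers were higher in classical monocyte-like cells, and free RNA may bring a median of 26.3% of the increase, with quartiles of 2.34% and 113%, which leaves it undecided over the 8 genes. It could bring all of the increase of S100a9, at 104%, Retnlg, at 140%, and Ngp, at 444%, and 39.3% of that of S100a8 and 13.2% of that of Lcn2, while for the immature myeloid markers Prtn3 and Elane the median was 1.36%, which argues against it for these. For caught neutrophils the planned test gave a median of 0.339 of the mean share of S100a8 and S100a9 (upper quartile 0.470). Il1r2 rose by 1.85 of it and, in the test added afterwards, only 1 of the 5 most abundant lay under 0.25. These tests cannot decide, since S100a8 and S100a9 themselves rose by unlike shares of their neutrophil levels, 1.38% and 0.554%. Retnlg, G0s2, Hdc and Cxcr2 rose by 0.358%, 0.488%, 0.298% and 0.240% of theirs and Il1r2 by 1.79%, while Csf3r fell. Caught neutrophils thus stay open. For caught late neutrophil precursors the planned test gave a median of 0.0447 with an upper quartile of 1.96 and did not decide, while 4 of the 5 most abundant markers lay under 0.25, Ngp, Camp and Ltf at 0.0364, 0.0260 and 0.0531, and Lcn2 at 2.59, which argues against them as the source of the increase of S100a8, S100a9 and Lcn2. A monocyte state with granule genes is a hypothesis that these tests leave open.

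For the other counts the same 10 splits are too few for a share under 0.05. Classical monocyte-like cells had 198 genes in the real split and 0 in the highest other, and whole libraries 1669 and 4. Neutrophil-like cells had 0 and 4, and T, NK and B cell-like cells 0 and 0. Alveolar macrophage-like cells had 0 in the real split and 356 when normal lung replicates 1 and 2 and AML lung replicate 1 were set against the rest, which points to a structure of the samples. Those are the libraries with the highest median UMI count per barcode. They also had the lowest free RNA levels in this class by the highest of the marker lists, at 1.12%, 1.61% and 0.881%. Normal lung replicate 3 and AML lung replicates 2 and 3 stood at 14.0%, 21.6% and 51.1%. Which of these lies behind the split was not tested.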

How the results depend on the processing

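The share without nonclassical monocytes and the full set of alternatives for nonclassical monocytes were chosen after seeing the data, and the other alternatives were planned. Over 16 alternatives, the 85 named genes past the threshold kept their sign in every setting that tested them. All 85 were chosen as past the threshold, and the largest changes also for no overlap between groups. This choice makes a change of sign unlikely, so the kept signs say little about stability. DESeq2, RLE size factors, no filter, at least 500 genes, under 5% mitochondrial UMIs, doublets kept and leaving out AML lung replicate 3 ended none of their calls. Marker score naming ended 19 of 58, equal cell numbers 10 of 54 and resolution 2 ended 4 of 58. Leaving out normal lung replicates 1, 2 and 3 ended 42 of 76, 60 of 85 and 33 of 85, and AML lung replicates 1 and 2 ended 31 and 15 of 85. Of 192 alternative counts of changed genes 109 lay within 1.5 times of the reported one, 58 above and 25 below. Most of the 109 come from comparisons without a changed gene. There an alternative that also called none was counted as within this range. The 109 therefore say little about how stable the counts are in comparisons that had changed genes. Of 209 alternative shares 199 moved by less than 1 SD. Among them, 15 with the replicate number as a block could not move, since the block leaves the difference of means unchanged. Another 15, without the immature myeloid class, could not move either, since no cluster took that name. The causes of the changes below were not tested.

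DESeq2 called 1225 genes in nonclassical and 582 in classical monocytes, 161 in interstitial and 130 in alveolar macrophages, 85 in neutrophils, 10 in T, 64 in NK and 15 in B cells, 55 in cDC1, 47 in cDC2, 14 in pDC, 4 in ILC2, 5 in mature DC, 350 in endothelial cells and 3493 in whole libraries. Without the low count filter edgeR called 1852, 1220 and 556 in nonclassical monocytes, classical monocytes and interstitial macrophages, 427 in neutrophils, 15 in NK cells, 360 in cDC1, 264 in cDC2, 409 in pDC, 132 in ILC2, 139 in mature DC and 182 in endothelial cells. With doublets kept interstitial macrophages had 46, neutrophils 36 and T cells 1. Named by marker score, nonclassical monocytes had 479 and interstitial macrophages 0. With equal cell numbers interstitial macrophages had 6 and NK cells 2.

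Leaving out each library in turn gave 110 to 1933 genes in nonclassical and 18 to 1048 in classical monocytes, 0 to 89 in interstitial macrophages, 0 to 3122 in whole libraries, 0 to 125 in neutrophils, 0 to 45 in NK cells, 0 to 1 in alveolar macrophages, 0 to 3 in cDC1, 0 to 9 in cDC2, 0 to 2 in pDC, 26 to 286 in ILC2 and 0 to 117 in mature DC. Without normal lung replicate 1 interstitial macrophages gave no value of their own, since it was already left out. The values for ILC2 and mature DC, and those of interstitial macrophages and pDC without a normal library, come from fits with 1 library in a group. ILC2 and mature DC could not be tested without AML lung replicate 1 or normal lung replicate 1, and pDC not without normal lung replicate 2.

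The replicate numbers were not taken to pair the samples, since same-numbered libraries deviated together by correlations of 0.213, -0.122 and -0.0815 over whole libraries. Only in T cells did all 3 pairs exceed 0.1, and there normal replicate 2 correlated better with AML replicate 1, at 0.442, than with its own number, at 0.116. With the replicate number as a block edgeR called 349 genes in classical monocytes, 239 in interstitial and 34 in alveolar macrophages, 269 in T, 55 in NK and 71 in B cells, 232 in pDC, 4 in cDC1, 1 in cDC2 and 94 in whole libraries, and 17 of the 85 named genes were not called with the block.

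Shares moved by more than 1 SD without nonclassical monocytes in the total, where AML minus normal was -4.32 percentage points for B, 2.92 for T and 1.87 for NK cells, 0.195 for cDC1, 1.495 for interstitial macrophages and 1.90 for late neutrophil precursors. By marker score it was -0.542 for ILC2, 0.808 for cDC2 and 1.60 for the precursors, which had 1.47 at resolution 2. Of 87 list calls by camera 0 held with an estimated correlation and 5 with fry, which made 6 in all, the other being extracellular matrix remodelling in neutrophils (adjusted p = 0.0483 by fry and 0.234 by camera). Of 756 alternative values of these calls 495 stayed past the threshold and 1 reversed, the immediate early and heat shock list in B cells, higher with adjusted p = 0.0380 and lower without AML lung replicate 3 with adjusted p = 0.0373, the range over left-out libraries being 0.000800 to 0.223. Depth limits AML lung replicate 3, at a median of 1067 UMIs per barcode.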

Other observations

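The genes below were singled out after their values were seen, and no explanation was tested for them. In nonclassical monocyte-like cells Spic, a transcription factor of iron-recycling macrophages, had a log2 change of 2.84 (SE 0.38, edgeR adjusted p = 0.00551). In whole libraries Spic stood at 56.8, 45.3 and 21.6 CPM in AML lung and at 2.46, 1.43 and 2.25 CPM in normal lung. Ngp stood at 411, 107 and 186 CPM in AML lung and at 0.576, 26.7 and 10.2 CPM in normal lung. Elane was at 4.44, 2.71 and 1.51 CPM in AML lung, with a single UMI over the 3 normal libraries. Of the 10 measured immature myeloid markers 3 were higher in whole libraries, Prtn3, Elane and Ctsg, and the stem and progenitor genes Kit and Cd34 did not pass edgeR's adjusted threshold, Kit at 7.24, 4.93 and 12.2 CPM in AML lung and 15.1, 21.8 and 20.6 CPM in normal lung.

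Haemoglobin transcripts divided the libraries across the groups. Hbb-bs stood at 641 and 361 CPM in normal lung replicates 2 and 3 and 378 CPM in AML lung replicate 3, and at 0.0961, 0.102 and 0.0301 CPM in normal lung replicate 1 and AML lung replicates 1 and 2. The surfactant gene Sftpc, of alveolar epithelium, ranged from 0.631 CPM in AML lung replicate 2 to 102 CPM in AML lung replicate 3.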
